A study of Haloferax volcanii with 6 samples.

How the data were processed

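Ribosome footprints and total RNA of Haloferax volcanii strain H119 were sequenced as 6 libraries. Per the labels' protocols, cells were grown aerobically at 45 °C in rich medium to an optical density of 0.4, RNA was extracted with hot phenol, total RNA was depleted of rRNA and fragmented, and footprints were selected by size; adapters were then ligated and the cDNA amplified by PCR. Samples were grouped by the labels into MNase_RIBO and MNase_RNA (2 libraries each) and RNaseI_RIBO and RNaseI_RNA (1 library each). The labels call the MNase RNA libraries biological replicates and do not say whether the footprint libraries come from separate cultures, so that p-values measure the spread between these libraries, which may in part be technical.

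The deposited main table lists 22369 features on 5 replicons, the main chromosome and plasmids pHV1 to pHV4, and 152 of its lines were empty in the copy used here. Its RPKM columns give the authors' reads scaled to CDS length and to mapped reads, per the file headers; from the values, the mapped reads are those of the feature's own replicon and not of the library. The deposited ratio columns (TE) equal the authors' footprint RPKM divided by RNA RPKM of the same experiment. The deposited probability column is a fraction given by the REPARATION caller of reading frames, and the deposited score column holds the score of the DeepRibo caller, per the file headers. Per the submitters' processing notes, bcl2fastq 2.20.0.422, cutadapt 2.1 and SAMtools 1.9 were used. The aligner, the read counter, the genome build, the treatment of reads with several matches and the settings of both callers are not given in the sources used here, so reads of near-identical genes cannot be assigned with certainty, and coordinates are those of the deposited table. Separate tRNA and rRNA tables, with RPKM made by the authors in another run, were used for values only; there the MNase column was taken as a library of its group with no number. A total of 6 columns of these tables name no sample of the series and were not used.

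Because deposited RPKM is scaled per replicon, values of the same message on different replicons are not comparable: the 6 CDS of pHV2 have median deposited values of 39092 to 148657 RPKM on 13 to 42 reads. Whole reads were therefore recovered from the size of 1 read on each replicon in each library, with all values checked lying within 0.1 of a whole number, and RPKM was computed anew from the reads of the whole library. The unit assumed when the tests were planned was RPKM over the library, so that the planned test was kept on the recomputed values, and the deposited values were run as an alternative. Mapped reads per library came to 2461042 to 10172439 and the median annotated CDS had 31 to 506 reads. Shares of a single library are given with 95% Wilson intervals, which cover counting error only, since PCR copies are not independent molecules.

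Annotated features without an intact reading frame (167) were set aside, which left 3884 CDS; small CDS are those of 70 codons or fewer. Of the 3884, 3780 were matched by locus tag to the gene table of assembly ASM2568v1, and 467 had a symbol. Tests used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), for CDS with a mean of at least 10 RPKM (3313 CDS, 228 of them small), each library centred on its median CDS. A model with 4 group means was fitted, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. The single RNase I libraries are assumed to vary like the MNase libraries. Log2 values are on the scale of RPKM + 1, which understates differences of low genes, and are relative to the median CDS, so they do not measure absolute efficiency; the median ratio before centring was 1.09, 5.80 and 1.55 in the MNase 1, MNase 2 and RNase I experiments. The contrasts were footprint against RNA in MNase, and RNase I against MNase in the ratio, the footprints and the RNA. In data simulated for the MNase contrast with 3350 genes, 40.6% of 2-fold and 98.9% of 4-fold changes were recovered, with 6 false calls (4.32%). The simulation used a single dispersion of 0.0414 for all genes and both assays, the median in the MNase pairs. It may overstate recovery in the real libraries, where 23.1% of CDS differed over 2-fold between the MNase RNA replicates and 0 of 3313 CDS passed.

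The deposited ratios divide libraries of the same number, though the labels do not say that these share a culture. Whether the numbers pair the libraries was checked from each library's deviation from the mean of its assay across genes: the footprint and RNA library of the same experiment correlated at 0.25 (MNase 1), 0.45 (MNase 2) and 0.30 (RNase I), so that the blocked counts are given beside the unblocked ones. The check was made after the blocked counts were known, and RNaseI_RIBO also correlated at 0.25 with MNase_RNA replicate 1.

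Gene lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry. Camera compares a list with the other CDS; fry asks only whether a list moves on balance, relative to the median CDS by the centring. Of 44 lists, 23 were fixed before the data were examined: start codons ATG, GTG and TTG, a Shine-Dalgarno match of at least 4 bases in the 15 bases upstream, small CDS, the replicons CHR, pHV1, pHV3 and pHV4, large ribosomal proteins, translation factors, other respiratory chain, TCA cycle, chaperones, proteasome, archaella and chemotaxis, S-layer and glycosylation, CRISPR-Cas, transcription regulators, amino acid synthesis, cell division, protein export, and DNA replication and repair. The other 21 were added after the gene symbols had been read. Among them are a hydrophobic stretch (19 residues with a mean hydropathy of at least 1.8) and 2 CxxC motifs. Fixed lists with fewer than 3 tested members, or which need product names, were not analysed here. Lists were matched by symbol.

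The rule for named genes was fixed before the data were examined. It takes the 6 highest and 6 lowest CDS of the main contrast with the same direction in both MNase pairs and the 6 of each with a symbol (by smallest p where fewer pass), the 2 most expressed and the 2 most different members of each list, 5 small CDS by footprint level and 3 at each end of the ratio, and the 6 unannotated frames with the highest footprint level that pass in all experiments. Of the list members, those of lists with an unadjusted camera p under 0.05 are named, a restriction made after the values were seen. The thresholds of 10 RPKM and a ratio of 0.5 were applied to annotated CDS and to 17144 unannotated frames with 15296 stop codons; 1174 further predictions share the stop of an annotated feature and were left out.

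Alternatives fixed in advance were other pseudocounts, filters, centring and variance settings, leaving out each MNase library, the replicate number as a block, the RNase I experiment added to make 3 libraries against 3, other limits for small CDS and other thresholds. Alternatives added after seeing the data were deposited RPKM with centring, voom weights on recovered reads with and without MNase_RNA replicate 2, and thresholds on deposited RPKM or without either MNase pair. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.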

Results

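Ribosome footprints and total RNA were sequenced from Haloferax volcanii, an archaeon that lives in concentrated salt, grown without treatment in rich medium at 45 °C to an optical density of 0.4. The cells were of strain H119, a laboratory strain known for deletions of genes of pyrimidine, tryptophan and leucine synthesis. Ribo-seq sequences the stretches of mRNA that ribosomes shield from a nuclease, so that the level of footprints over a coding sequence (CDS), set against its RNA level, measures how densely the message was occupied by ribosomes. The 6 libraries form 4 groups: footprints made with micrococcal nuclease (MNase_RIBO, 2 libraries), the RNA libraries belonging to them (MNase_RNA, 2 libraries), footprints made with RNase I (RNaseI_RIBO, 1 library) and its RNA library (RNaseI_RNA, 1 library). The series title names the small proteins of the organism as the subject. The deposited table held 3884 intact annotated CDS, 273 of them of 70 codons or fewer, and 17144 predicted reading frames that share no stop codon with an annotated gene.

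The footprint libraries were deeper than the RNA libraries. The reads recovered from the table came to 9953199 and 5654245 for the MNase footprint libraries, 10172439 for the RNase I footprint library, 3980686 and 3350638 for the MNase RNA libraries and 2461042 for the RNase I RNA library. Annotated CDS took 89.1%, 80.5% and 88.1% of the reads in the footprint libraries. In the RNA libraries they took 61.3% and 16.6% (MNase replicates 1 and 2) and 48.5% (RNase I), so that the median CDS had 196, 31 and 84 RNA reads. A single unannotated frame of 59 codons at 936236 to 936412 on the plus strand of the main chromosome, between HVO_1026 and HVO_1027, took 22.7% of the reads of MNase_RNA replicate 2 (95% Wilson interval 22.67 to 22.76), against 5.84% in replicate 1 (5.82 to 5.86) and 6.39% in the RNase I RNA library (6.36 to 6.42). In the reference gene order the gene of the signal recognition particle RNA, ffs, lies between the same 2 neighbours. The frame held 0.00816%, 0.00921% and 0.0377% of the footprint reads.

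**Figure D1:**
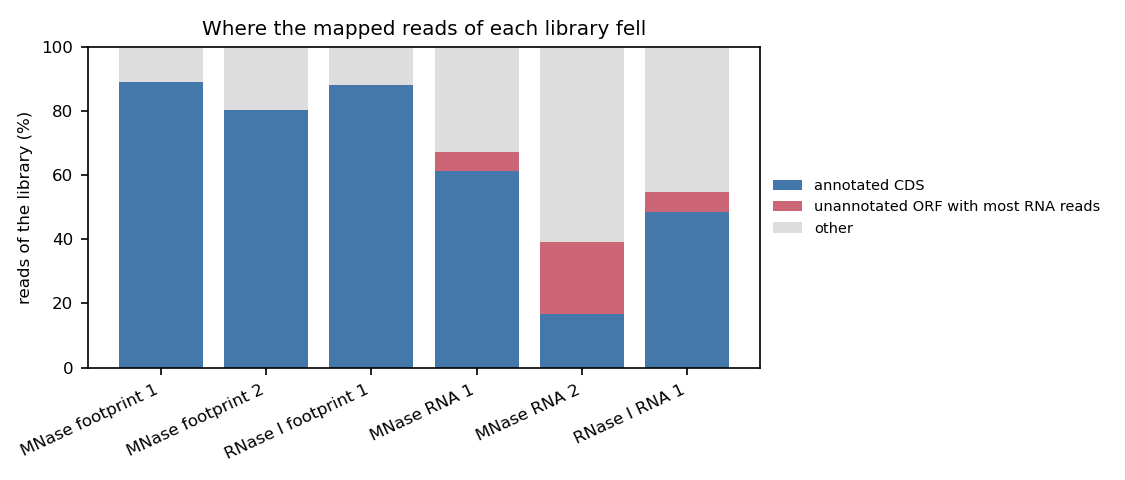
Share of the mapped reads of each library, in percent, that fell in annotated CDS (blue), in the unannotated frame with the most RNA reads (red) and elsewhere (grey), for the 3 footprint and 3 RNA libraries. Annotated CDS take 80.5% to 89.1% of footprint reads, and MNase RNA replicate 2 stands lowest at 16.6%, with 22.7% of its reads in the red frame.

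The genes known to be deleted in H119 were read in every library as a check of the labels. The pyrE gene HVO_0333, of pyrimidine synthesis, had 2, 2 and 5 footprint reads and 6, 5 and 4 RNA reads in the libraries MNase 1, MNase 2 and RNase I, or 0.378 to 0.926 RPKM in footprints against a median CDS at 65.5 to 71.9 RPKM. The trpA gene HVO_0789, of tryptophan synthesis, had 39, 38 and 72 footprint reads and 20, 1 and 8 RNA reads. The leuB gene HVO_1502, of leucine synthesis, had 206, 62 and 182 footprint reads and 68, 5 and 18 RNA reads, which placed it between the 5.92 and 25.0 percentile of all CDS. How much of each gene was removed is not given in the sources used here, so reads from a part that remains cannot be set apart. The 6 CDS of plasmid pHV2, which the parent of the strain is known to have lost, held 24, 42 and 13 footprint reads and 29, 21 and 25 RNA reads in all. The deposited values of stable RNAs were low in every library used. Of 6 rRNA genes, 5 were listed at 0 in an MNase footprint library and 3 in the RNase I footprint library, and the highest value was 56.4 RPKM, in an MNase RNA library. Of 43 tRNA genes, 32 and 33 were listed at 0 in those footprint libraries, and the highest values were 120 RPKM in both RNA libraries, for HVO_3052.

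The first comparison asked which genes carried more or fewer footprints than their RNA level gives, relative to the median CDS, in the MNase experiment. The highest values were those of radA, the recombinase of homologous recombination, and of HVO_0062. For radA, at 5570 ± 683 RPKM in footprints and 374 ± 341 RPKM in RNA (SD, n = 2), the ratio stood 8.21-fold above the median CDS, a log2 ratio of 3.04 with a standard error of 0.40. The SDs of RNA levels, here and below, are of RPKM before centring. They include the difference between the MNase RNA libraries as wholes, where the median CDS stood at 70.7 and 12.5 RPKM. For HVO_0062 the log2 ratio was 2.89 with a standard error of 0.44. The gene of the S-layer glycoprotein that forms the cell envelope, csg, held the highest footprint level of its list, at 23900 ± 3327 RPKM (SD, n = 2), and stood 6.36-fold above the median CDS. Further CDS with a high ratio, taken by the smallest p, were HVO_A0378, HVO_1212, HVO_0743 and HVO_0379B, with log2 ratios of 2.52, 2.43, 2.41 and 2.32. Among genes with a symbol they were aglF, of protein glycosylation, cas7b, of the CRISPR interference complex, and pyrI and pyrB, the subunits of aspartate carbamoyltransferase in pyrimidine synthesis, with log2 ratios of 2.74 (3.36 and 2.13 in the MNase pairs), 2.54, 2.19 and 1.89. The peroxiredoxin gene bcp stood 3.73-fold above the median CDS.

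At the other end, the CDS with the smallest p were HVO_A0638, HVO_0638, HVO_1147, HVO_2214, HVO_2200 and HVO_1763, with log2 ratios of -3.61, -3.03, -2.84, -2.53, -2.44 and -2.07. Some CDS with a larger p had lower ratios, among them the small HVO_0197A at -5.25. HVO_1147 was well expressed as RNA, with 911.7 and 104.5 RPKM in the 2 MNase RNA libraries, and held 92.4 and 111.3 RPKM of footprints. HVO_A0638 held few footprints, at 4.53 and 2.39 RPKM, and stood at -2.76 and -4.47 in the MNase pairs. Among low genes with a symbol, those with the smallest p were metX of methionine synthesis (-1.80, with -2.393 and -1.201 in the MNase pairs), the RNA cyclase gene rtcA (-1.79), the translesion DNA polymerase gene dinB (-1.78), thiI of tRNA thiolation (-1.70), larB (-1.51) and thiL of thiamine synthesis (-1.27). The genes named here had the same direction in both MNase pairs, as the rule for naming them required. In the RNase I experiment, which played no part in the choice, each lay on the same side of the median CDS, from 0.98 for cas7b to 2.00 for aglF among the high genes and from -3.06 for HVO_A0638 to -0.07 for dinB among the low ones.

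**Figure D2:**
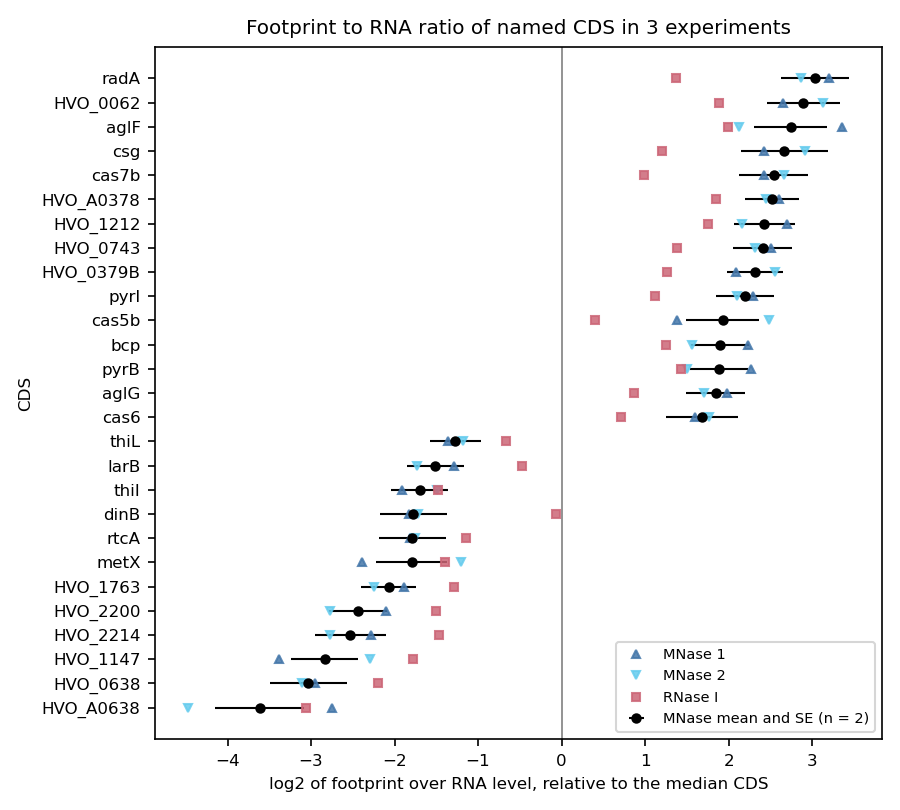
Log2 of the footprint over the RNA level, relative to the median CDS (horizontal axis), of the CDS named by the fixed rule for high and low ratios and of named S-layer, glycosylation and CRISPR-Cas genes (vertical axis). Black points with bars are the MNase mean and its standard error (n = 2), triangles the MNase pairs and squares the RNase I pair, for which radA stands at 1.37 against an MNase mean of 3.04.

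No single gene passed the threshold in this comparison. Of 3313 CDS tested with limma, 0 had an adjusted p under 0.05, the lowest adjusted p was 0.0651, and 987 had an unadjusted p under 0.05; voom weights on the recovered reads also gave 0. The same fit called CDS when an MNase_RNA replicate was left out, but its spread then comes from the 2 MNase footprint libraries alone. Between those 5.07% of CDS differed over 2-fold, against 23.1% between the MNase RNA replicates. The lone RNA library may thus be given too small a spread, and these calls are not set beside the 0. With the replicate number as a block, a fit also written down in advance, 387 CDS were higher and 360 lower (lowest adjusted p = 0.0156, limma). The correlations that pair the libraries were computed after this count was known. The blocked fit was not run without single libraries. With the RNase I experiment added as a further footprint and a further RNA library, an alternative written down in advance, 403 CDS were higher and 369 lower, among them radA, HVO_0062, aglF, pyrB, HVO_0638 and HVO_2200 (adjusted p = 0.00868 each). With the experiment as a block as well, 611 were higher and 558 lower. The log2 ratios of single genes correlated between experiments across the 3313 genes, which are not independent replicates, with Pearson's r of 0.71 between the MNase pairs and 0.72 between each of them and the RNase I pair.

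Gene lists were used to ask which functions stood high. Lists of function were matched by symbol, which 467 of the 3884 CDS have, but were compared with all other tested CDS. Whether genes with a symbol stand high in general was not tested. The list of S-layer and protein glycosylation genes, 13 genes for the envelope protein and for the enzymes that attach its sugars, had a median log2 ratio of 1.37, or 2.58-fold above the median CDS. It was higher as a set in camera, a competitive gene set test with a preset correlation of 0.01 (adjusted p = 0.00428 over 44 lists), but not with an estimated correlation (adjusted p = 0.762). Of its members 12, 11 and 10 lay above the median CDS in the experiments MNase 1, MNase 2 and RNase I. Beside csg and aglF, aglG stood at a log2 ratio of 1.85, with 940 ± 208 RPKM in footprints and 151 ± 150 RPKM in RNA (SD, n = 2). The CRISPR-Cas list of 7 genes, an adaptive defence system encoded on plasmid pHV4, had a median log2 ratio of 1.68 (adjusted p = 0.0228 in camera, and adjusted p = 0.762 with an estimated correlation), and 7, 6 and 6 members lay above the median CDS. Within it cas7b, cas5b and cas6, which belong to the complex that processes and carries the guide RNA, stood at 2.54, 1.93 and 1.68. Of the 44 lists, 4 passed camera with the preset correlation, the other 2 being start codon classes, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. Adjusted over all genes, 0 members of either list passed; adjusted over the list alone, 6 of 13 and 4 of 7 were higher and 0 lower. Without MNase_RNA replicate 1 both lists missed the threshold (adjusted p = 0.0645 for both), with a median of 0.90 for S-layer and glycosylation and of 1.99 for CRISPR-Cas. The CRISPR-Cas list also missed it with the RNase I experiment added (median 1.36, adjusted p = 0.0851) and with deposited RPKM, uncentred (2.14, adjusted p = 0.0651) or centred (0.98, adjusted p = 0.202).

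Other lists gave high medians that did not pass after adjustment over the 44 lists. The aminoacyl-tRNA synthetases, 15 genes for the enzymes that load tRNAs, had a median log2 ratio of 0.57 (adjusted p = 0.107, camera), with thrS at 1.43, proS at 1.54 (0.86 and 2.21 in the MNase pairs) and aspS at 0.57; with the RNase I experiment added, 3 of the 15 passed singly, all higher, among them thrS and proS (adjusted p = 0.00960 and 0.0160). Of the fixed list of citric acid cycle genes, the 5 tested had a median of 0.88, with mdh at 0.85, icd at 0.88, sucC at 0.88 (0.29 and 1.47 in the MNase pairs) and sucD at 1.12, and each of the 5 lay above the median CDS in all 3 experiments. The 8 ribosomal protein genes with a symbol had a median of 0.88, with log2 ratios of 2.202 for rplX, 0.84 for rpsJ, 1.27 for rpmC and 0.57 for rpl12p. Most of this came from the second MNase pair: the 2 pairs gave 1.21 and 3.19 for rplX (0.34 in RNase I), 0.52 and 2.03 for rpmC (0.07) and -0.07 and 1.21 for rpl12p (-0.25), and rpl12p stood at -0.00426 under quantile normalisation. The 3 phosphate uptake genes had a median of 1.06, with phoU at 1.06 and HVO_2378, whose reference symbol is pstB, at 1.56 (0.93 and 2.18 in the MNase pairs). The 5 transcription regulators had a median of 0.98, with HVO_2029 at 1.91 and HVO_0240 at 1.54; both have the reference symbol lrp. Adjusted over the list alone, 3 of these 5 regulators were higher and 0 of the 5 citric acid cycle genes were. The adjusted p was 0.189 for each of these 4 lists.

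CDS that begin with GTG had a median log2 ratio of -0.46 (393 CDS), against 0.10 for those that begin with ATG (2912 CDS). Both classes passed camera with the preset correlation (adjusted p = 3.3e-05 for each, the GTG class lower and the ATG class higher), but neither with an estimated correlation (adjusted p = 0.369 for both). In fry, which asks whether a class moves on balance and does not compare it with other CDS, neither passed (adjusted p = 0.0802 for both). The difference had the same sign in each experiment, with medians of -0.50, -0.36 and -0.32 for GTG and of 0.08, 0.13 and 0.04 for ATG in MNase 1, MNase 2 and RNase I. Of the 12 low genes named above, HVO_A0638, HVO_0638, HVO_2200, HVO_1763, dinB and thiI begin with GTG, as do 393 of all 3313 tested CDS. The 12 were picked by low ratios in the same libraries and are not separate support. Adjusted over all genes, 0 CDS of either class passed, and with the RNase I experiment added 88 GTG-start CDS were lower and 22 higher, against 277 and 381 ATG-start CDS. A Shine-Dalgarno match of at least 4 bases anywhere in the 15 bases before the start went with no such difference (median 0.01 over 1058 CDS, adjusted p = 0.797, camera). Messages can pair with the ribosome through this sequence, but no spacing to the start was required of the match. Whether these bases lie in the message was also not tested, so the result does not show whether such pairing matters here.

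**Figure D3:**
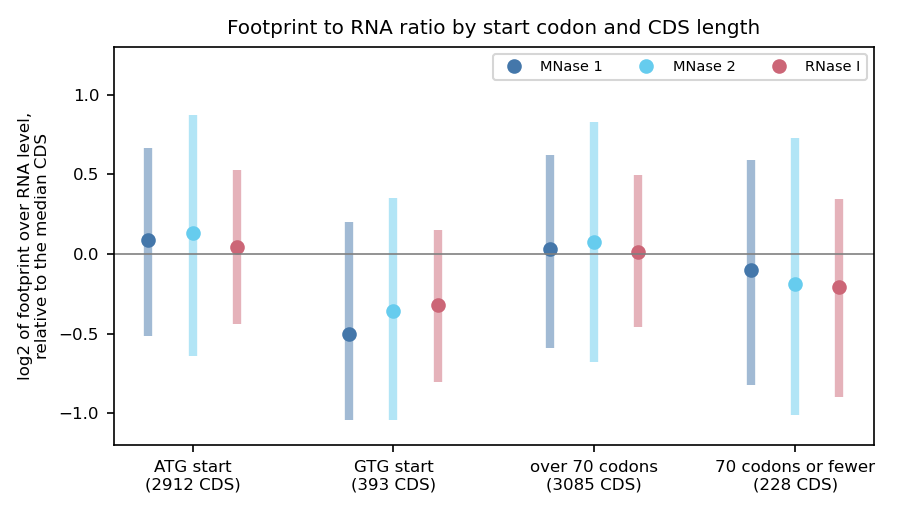
Median (points) and quartiles (bars) across CDS of the log2 footprint over RNA level, relative to the median CDS (vertical axis), for CDS by start codon and by length (horizontal axis), in the MNase 1, MNase 2 and RNase I experiments. GTG-start CDS have medians from -0.50 to -0.32, and CDS of 70 codons or fewer from -0.21 to -0.10.

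Small CDS, of 70 codons or fewer, were at higher levels than longer ones in both assays. Their median was 97.4, 115 and 102 RPKM in the MNase 1, MNase 2 and RNase I footprint libraries against 68.0, 63.5 and 70.3 RPKM for longer CDS, and 102, 28.8 and 84.1 RPKM against 68.1, 11.9 and 47.1 RPKM in the RNA libraries. The highest footprint levels among them were those of HVO_1992 (65 codons, 21993 ± 2752 RPKM), HVO_0115 (51 codons, 18732 ± 7229 RPKM), HVO_0582 (62 codons, 12344 ± 3054 RPKM), HVO_3011 (38 codons, 10203 ± 10657 RPKM) and lysW (60 codons, 9540 ± 676 RPKM, with SD and n = 2 in each case), the last a carrier protein of amino acid synthesis. Among the CDS tested, log2 footprint to RNA ratios also varied more in small CDS, with an SD of 1.15 in the MNase mean against 0.955 in longer ones. Small CDS had fewer reads, with medians of 68 and 16 in the MNase RNA libraries against 208 and 32. How much of the wider spread is counting error was not tested. HVO_0197A, of 50 codons at 38.1-fold below the median CDS, had RNA at 3850 and 5563 RPKM and footprints at only 208 and 391 RPKM in the MNase libraries, and a log2 ratio of -5.25 in MNase (-4.30 and -6.21 in the pairs) and -2.69 in RNase I. HVO_1509 (34 codons) and HVO_0031 (57 codons) followed at -3.71 (-2.55 and -4.86) and -3.00 (-2.37 and -3.63). HVO_2550 (59 codons), HVO_2691 (68 codons) and HVO_2512 (70 codons) had the highest MNase means, at 2.87, 2.84 and 2.18. The order of these 3 rests on MNase_RNA replicate 2, where HVO_2550 had 40 reads and HVO_2691 had 1: they stood at 1.59, 1.36 and 2.51 in MNase 1, at 4.15, 4.33 and 1.85 in MNase 2 and at 1.27, 0.44 and 1.95 in RNase I. As a set, the 228 small CDS tested had a median log2 ratio of -0.12 against 0.06 for longer CDS, a difference that did not pass (-0.17, camera adjusted p = 0.388) and whose sign depended on the library. Adjusted over the list alone, 2 small CDS were higher and 13 lower. With an estimated correlation the adjusted p of camera was 0.941. The difference was -0.31 without MNase_RIBO replicate 2 and -0.40 without MNase_RNA replicate 1, and 0.0117 without MNase_RIBO replicate 1 and 0.0257 without MNase_RNA replicate 2.

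Thresholds often used for prokaryotic Ribo-seq, at least 10 RPKM in both assays and a footprint to RNA ratio of at least 0.5, were met by 1926 of the 3884 annotated CDS (49.6%) in both MNase replicates. Small CDS met them more often than longer ones, with 159 of 273 (58.2%) against 1767 of 3611 (48.9%), but the order differed between experiments: 68.9% of small and 75.3% of longer CDS passed in MNase 1, 65.6% and 54.4% in MNase 2, and 75.1% and 80.0% in RNase I. The limit in MNase 2 was the RNA library, where 1702 CDS lay under 10 RPKM, against 457 in MNase 1 and 617 in RNase I. Without the MNase replicate 2 pair, 2906 CDS passed. Of the 1926, 1907 also passed in the RNase I experiment. The ratio was not centred here. Among CDS at 10 RPKM or more in both assays, its limit excluded 24 in MNase 2, against 329 in MNase 1 and 73 in RNase I. With the ratio centred on the median CDS, 1661 CDS (42.8%) passed in both MNase replicates.

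The choice of nuclease was the next comparison. No gene passed the threshold between RNase I and MNase in its footprint to RNA ratio (0 of 3313 CDS in limma, 21 at an unadjusted p under 0.05), in its footprint level (0, 99 unadjusted) or in its RNA level (0, 14 unadjusted), and voom also gave 0 in each; with 1 library per RNase I group, these tests assume that it varies like the MNase libraries. In the same fit the MNase contrast of 2 against 2 libraries also called 0, with ratios up to 38.1-fold from the median CDS. The counts of 0 between nucleases thus do not show that the nucleases agree. Footprint levels followed one another across the 3313 genes, with Pearson's r of 0.96 between the MNase replicates, 0.96 between MNase replicate 1 and RNase I and 0.94 between MNase replicate 2 and RNase I. In RNA the corresponding values were 0.87, 0.97 and 0.91, so that MNase_RNA replicate 2 was the library farthest from the rest. In footprints 5.07% of CDS differed over 2-fold between the MNase replicates, and in RNA 23.1% did.

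Of the predicted reading frames without an annotated stop codon, 8123 passed the same thresholds in both MNase replicates, and 7382 did so in the RNase I experiment as well. Most overlap an annotated gene on the same strand, whose reads they share: 2413 of the 8123 do not. Of these, 887, with 822 distinct stop codons, overlap no annotated gene on either strand, and 767 of those stops close a frame of 70 codons or fewer. These counts rest on single pairs and on the scale of the ratio. Without the MNase replicate 1 pair, 3940 passed with no overlap on the same strand and 1378 with none on either strand. Without the replicate 2 pair, 12417 passed in all and 4069 with no overlap on the same strand. With the ratio centred on the median CDS, 1270 and 564 passed with no overlap on the same and on either strand. The thresholds alone do not show that a frame is coding. Predicted frames inside an annotated CDS on its other strand also drew reads. Where the CDS had at least 100 RPKM, they held a median of 8.61% to 11.7% of that CDS's footprint level and of 5.24% to 19% of its RNA level. How many of these frames passed the thresholds was not counted, and whether they are translated was not tested. The 6 frames with the highest MNase footprint levels among those passing in all experiments were led by a frame of 13 codons, ATG start, at 1857669 to 1857707 on the minus strand of the main chromosome, in the space between HVO_2011 and HVO_2012. It held 58636 and 226760 RPKM in the MNase footprint libraries, 34392 RPKM in RNase I footprints and 46732, 50446 and 57876 RPKM in the RNA libraries. Before centring, its footprint to RNA ratio was 1.25, 4.5 and 0.594 in MNase 1, MNase 2 and RNase I. The median CDS stood at 1.09, 5.80 and 1.55, so the frame lay below it in MNase 2 and RNase I. Frames 2 to 6 in rank lie inside annotated genes and cannot be told from them: at 1925522 to 1925584, 1925102 to 1925299, 1926057 to 1926092 and 1925945 to 1926013 on the plus strand of the main chromosome within csg, and at 131073 to 131147 on the minus strand of pHV4 within HVO_A0133. Among frames that overlap no annotated gene, 2 were chosen after their values were seen. A frame of 13 codons on the plus strand of pHV4 at 207912 to 207950, directly before cas6, held 20601 ± 6726 RPKM of footprints and 1382 ± 1435 RPKM of RNA (SD, n = 2). Because cas6 starts at 207954 on the same strand, reads of this frame may not be separable from those of cas6. A frame of 27 codons lay at 329290 to 329370 on the plus strand of the main chromosome, following the ribosomal protein gene rpsJ. It held 10806 ± 9359 RPKM of footprints and 2502 ± 1965 RPKM of RNA, with 4189 and 17424 RPKM in the MNase footprint libraries. Its ratio before centring was 1.08, 15.7 and 2.00 in MNase 1, MNase 2 and RNase I. It thus lay near the median CDS in MNase 1 and above it in MNase 2 and RNase I. The authors' DeepRibo column cannot support frames of this kind, since it lists a call for 2162 of 2163 of them before any threshold and so for 724 of the 724 that passed in all experiments; their REPARATION column lists 1 before and 0 after.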

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

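The gene list tests between nucleases, the comparison with all pHV4 CDS and the relation with codon count were chosen only after the values they measure had been seen; the other tests in this part were written down before.

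Some gene lists stood apart between RNase I and MNase in their footprint to RNA ratio in camera with the preset correlation, while no single gene passed. None of the 7 held with an estimated correlation (adjusted p = 0.977 for pHV1 and pHV4 and 0.641 for the other 5), and with 1 footprint and 1 RNA library for RNase I a difference between nucleases cannot be separated from one between single libraries. Lower with RNase I were the lists of pHV1 (median log2 difference -0.49, adjusted p = 0.000253), pHV4 (-0.32, 0.000893), CRISPR-Cas (-0.97, 0.00278), S-layer and glycosylation (-0.74, 0.00991) and archaella and chemotaxis (-1.09, 0.0185). Higher were CDS of the main chromosome (0.0137, 0.000253) and CDS with a hydrophobic stretch (0.0570, 0.0455). These are adjusted p-values of camera with the preset correlation. The pHV1 and pHV4 differences rest mostly on the first MNase experiment, with medians of 0.89 and 0.04 in the MNase pairs and -0.20 in RNase I for pHV1, and of 0.32, -0.00319 and -0.10 for pHV4. The main chromosome lay at 0.03 in RNase I, between -0.06 and 0.07 in the MNase pairs, and the archaella list has 3 genes. Separately, of the 167 annotated features without an intact reading frame, which no comparison used, 124 had more than 3 reads in each of the 6 libraries.

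The lower footprint to RNA ratio of GTG-start CDS was weighed against 3 technical explanations. Level and length do not account for it as a whole: within classes of mean RPKM and codon count the GTG minus ATG mean was -0.42 with a standard error of 0.05, against -0.52 without classes. GC content taken by itself may carry part of it but not all, since within 10 classes of GC content the mean was -0.34 with a standard error of 0.05. The standard errors given here come from resampling CDS, which are not independent replicates. Level, length and GC content were not held fixed together, so how much they account for jointly stays open. An annotated start placed too far upstream stays open: in CDS with a shorter predicted form, the log2 ratio before the shorter start minus that after it had a median of -0.07 in 71 GTG-start and -0.16 in 394 ATG-start CDS. The drop was thus not larger in GTG-start CDS, but the difference of 0.0887 has a standard error of 0.186, too wide to exclude it. No biological explanation was tested, since the start codon is not a group of the design.

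MNase_RNA replicate 2 stood apart from the other RNA libraries. Fewer reads do not account for it: MNase_RNA replicate 1 thinned to the reads of replicate 2 still had a correlation of 0.964 across genes with the RNase I RNA library, against 0.905 observed for replicate 2. More reads from short transcripts may contribute and stay open: the deviation of replicate 2 had a Spearman's rho of -0.159 with codon count across genes, which are not independent replicates, and a median of 0.40 in small CDS against -0.06 in longer ones. A difference between the cultures or in RNA preparation was not tested.

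The high ratios of the CRISPR-Cas and of the S-layer and glycosylation lists were set against the plasmid and the expression level. A shift of all of pHV4 would place the CRISPR-Cas list near the plasmid's median. The list's median of 1.68 (SD 0.86 across its 7 genes) lay 1.51 above the plasmid's 0.17. With deposited RPKM, scaled per replicon and then centred, the list stood at 0.98 (SD 0.83), 1.74 above the plasmid's -0.76. The gap of 1.51 exceeds the SD and argues against such a shift as the whole cause in the MNase experiments. It exceeds the bound set for excluding the shift by less than the SD, so the shift is not excluded. The gap of 1.74 is not separate support, since scaling per replicon moves all pHV4 CDS of a library alike. The deposited values also changed the pHV4 CDS kept, from 397 to 556, and there the list did not pass (adjusted p = 0.202, camera). Expression level alone gave lower medians: 10000 random lists matched on mean RPKM had a median of 0.37 for CRISPR-Cas and 0.43 for S-layer and glycosylation. The lists lie at the 99.99 and 99.95 percentiles of these, which describes these libraries and not other cultures. The percentiles may be too high, since random genes were drawn singly while list members, such as neighbouring CRISPR-Cas genes, may vary together. Both lists were also chosen for this test by their high ratios in the same libraries. Dependence on the nuclease stays open, with medians of 1.38, 1.76 and 0.40 for CRISPR-Cas and 1.85, 0.90 and 0.46 for S-layer and glycosylation in MNase 1, MNase 2 and RNase I. No biological explanation was tested, since function is not a group of the design.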

How the results depend on the processing

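Chosen only after the data were seen were the settings with deposited RPKM after centring, with voom weights, and with thresholds on deposited RPKM or without either MNase pair. For the changes listed here the cause was not tested, except where a setting leaves out libraries or applies another threshold.

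In the MNase contrast the count of CDS past the threshold was 0, and it stayed at 0 in 10 of 18 alternatives. It was 216 with a pseudocount of 5 (114 higher, 102 lower), 1 with deposited RPKM and no centring, 772 with the RNase I experiment added and 317 with voom and without MNase_RNA replicate 2 (218 higher, 99 lower). Leaving out single MNase libraries gave 0 to 905. Between nucleases, deposited RPKM without centring gave 3 CDS for the ratio, 2 for footprints and 2 for RNA, deposited RPKM with centring gave 1 for footprints and 1 for RNA, and leaving out libraries gave 0 to 1 for RNA. The number of lists passing was 4, against 10 with deposited RPKM, centred or not, 7 with voom and without MNase_RNA replicate 2, 0 with an estimated correlation, 1 with fry, and 4 to 7 without single libraries. The adjusted p of CRISPR-Cas was 0.0651 with deposited RPKM uncentred, 0.202 centred, 0.0851 with the RNase I experiment added, 0.762 with an estimated correlation, and 0.00332 to 0.0645 without single libraries. For S-layer and glycosylation it was 0.762 with an estimated correlation, 0.203 with fry, and 8.2e-05 to 0.0645 without single libraries. For the ATG and GTG classes it was 0.369 with an estimated correlation and 0.0802 with fry, which does not compare a list with other CDS; both passed in the other 18 alternatives each.

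The difference of small from longer CDS, -0.17 and not past the threshold, was -0.30 among CDS of at least 50 RPKM (camera adjusted p = 0.105 over the lists, past the threshold only before adjustment) and -0.37 with quantile normalisation (adjusted p = 0.0335). It was 0.0138 with voom and without MNase_RNA replicate 2, and -0.40 to 0.0257 without single libraries; its adjusted p ranged from 0.0335 to 0.941. The count of annotated CDS meeting the thresholds, 1926, was 876 at 30 RPKM, 1229 at a ratio of 1, 3125 in any MNase replicate and 2145 to 2906 without one MNase pair. The count of unannotated frames, 8123, was 3703 at 30 RPKM, 4749 at a ratio of 1, 2413 without overlap on the same strand and 10674 to 12417 without one MNase pair. Of 947 values of 53 named genes over 18 alternatives, 680 kept direction and side of the threshold, 264 passed it with the same direction, and 3 changed sign: HVO_0582 (0.49) and thiL (0.0698) with deposited RPKM uncentred, and rpl12p (-0.00426) with quantile normalisation.

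With the replicate number as a block the MNase contrast gave 747 CDS (387 higher, 360 lower), and with the experiment as a replicate block over 3 libraries against 3 it gave 1169 (611 higher, 558 lower), where CRISPR-Cas had an adjusted p of 0.0896. The block changed no call of the 4 lists named here or of the small CDS. Depth was lower on the RNA side: the median CDS had 31 reads in MNase_RNA replicate 2.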

Other observations

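The 21 added lists were chosen after the gene symbols were read, and the count over other splits of the libraries was chosen after the result was seen.

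Further groups did not pass in the MNase footprint to RNA ratio after adjustment over the 44 lists (adjusted p from 0.343 to 0.943, camera), and many had medians above 0. Among enzymes and protein quality control, the medians were 0.74 for chaperones, 0.63 for the proteasome, 0.81 for iron-sulfur cluster assembly, 0.77 for glycolysis and gluconeogenesis, 0.76 for histidine breakdown, 0.54 for glycine cleavage, 0.34 for glycerol and dihydroxyacetone use, 0.17 for purine and pyrimidine synthesis, 0.18 for amino acid synthesis and 0.88 for other respiratory chain. In translation and export they were 0.57 for the large ribosomal proteins, 0.66 for translation factors, 0.53 for the completed list of translation factors and 0.25 for protein export, and 0.71 for archaella and chemotaxis. Near 0 lay DNA replication and repair (0.09), tetrapyrrole synthesis (0.13), cobalamin synthesis (0.06) and siderophore synthesis (-0.000494). Below it lay the fructose phosphotransferase system (-0.31), pentose uptake and breakdown (-0.31), small archaeal modifiers (-0.17) and cell division (-0.13); phenylacetate breakdown had a median of 0.31 and a mean of -0.10. Many of these medians changed sign between experiments, among them, in MNase 1, MNase 2 and RNase I, those of large ribosomal proteins (-0.07, 1.25 and 0.28), protein export (-0.32, 0.47 and 0.31), chaperones (0.34, 0.98 and -0.04), archaella and chemotaxis (0.36, 0.53 and -0.44), siderophore synthesis (0.97, -0.23 and -0.19), phenylacetate breakdown (0.28, -0.71 and 0.34) and cell division (-0.35, 0.12 and -0.23). The medians of amino acid, tetrapyrrole and cobalamin synthesis, glycerol and dihydroxyacetone use, DNA replication and repair, pentose uptake and breakdown, small archaeal modifiers and the 4 replicons did so as well. The replicons had medians of 0.02 (main chromosome), 0.40 (pHV1), 0.10 (pHV3) and 0.17 (pHV4).

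CDS whose protein has a hydrophobic stretch had a median of -0.15 over 775 CDS (adjusted p = 0.189, camera). CDS with 2 CxxC motifs, which can bind metal ions, had a median of -0.08 over 169, and those of 100 codons or fewer -0.12 over 59. The 7 TTG-start CDS had a median of -1.07, and 4 of them were lower adjusted over the list alone. Median, mean and test differed in sign for cobalamin and siderophore synthesis, phenylacetate breakdown, the main chromosome and the Shine-Dalgarno class.

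With 3 footprint libraries set against 3 RNA libraries, 772 CDS passed, and the highest count in the other 9 splits of the 6 libraries was 0. As many as 772 were found in 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05. The real split parts all 3 experiments; 3 of the other splits part as many and the remaining 6 keep libraries of an experiment together, and each of the 9 gave 0.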
